A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

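RNA was measured in 18 libraries from budding yeast of the BY4741 strain, in 6 groups of 3 biological replicates. Per the labels, the strains carried a tag on Rvb1 or on Rvb2, and in each tagged background the cells were wild type, lacked PIH1 or lacked TAH1. Cultures of 5 ml were grown in YPD, a rich glucose medium, at 30 °C until the OD600 lay between 1.2 and 1.5. Total RNA was extracted, RNA with a poly(A) tail was enriched with oligo(dT), and Illumina libraries were sequenced. The label of 1 library is not consistent in itself: replicate 1 of the Rvb2-tagged wild type is named so in its title, while its source field names Rvb1. The title was followed.

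Both tables were made by the authors and hold 7126 genes or other features in 18 columns, 1 per library; 375 features were at 0 in every library. The deposited normalized counts (unit: signal) are read counts per gene divided by a factor per library and rounded to whole numbers; the factors are not given. The deposited FPKM values (unit: score) are rounded to whole numbers too. Gene by gene they are proportional to the normalized counts: over 608 genes above 200 FPKM the log2 ratio of the tables had a median SD of 0.000748 across libraries. Per the submitters' processing notes, TopHat2 2.0.3, DESeq2 1.6.3 and the sacCer3 build were used. The gene annotation, the counting tool, the strand setting and any filter are not given in the sources used here.

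The normalized counts of a library summed to 4829249 to 5412654, and 6362 to 6518 features were above 0. Library factors were estimated from the spacing of the rounded values at 0.865 to 1.29, which put the assigned reads per library at 4464609 to 6245281. In a check on simulated tables, 9 of 10 estimated factors lay within 1% of the truth. The 10 most abundant genes took 8.69% to 11.6% of the counts. Reads carry no molecular identifiers, so floors cover counting error only. Identifiers were matched to the reference annotation of the same build, 6048 by locus tag and 112 by symbol; 966 had no match, 199 of them among the genes tested. Genes without a match are given by the identifier in the table, with no position.

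Comparisons were made with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), for 5825 genes with a mean of at least 10 over the 18 libraries. One model with 6 group means and an intensity trend was fitted to all libraries. There were 9 contrasts: each deletion against the wild type of its background, PIH1 against TAH1 deletion in each background, the wild types against each other, and the difference of each deletion effect between the backgrounds. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. The p-values measure the spread between these libraries. Errors of log2 changes are standard errors of the fit, and errors of normalized counts are SD, with n = 3 libraries per group. For a group with 0 in all libraries, the fold was computed against a floor of 3 normalized counts for the group mean.

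Of the 28 gene lists, 27 had at least 5 tested members and were tested in each contrast with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 243 tests. Camera with an estimated correlation was run beside it: 118 of the 243 tests passed with the preset correlation and 4 with the estimated one. Those 4 are the phosphate list in the Rvb1-tagged TAH1 deletion, in PIH1 against TAH1 deletion with tagged Rvb1 and in the TAH1 difference between backgrounds, and the iron list in the Rvb1-tagged TAH1 deletion. Subtelomeric genes are those within 30000 bp of a chromosome end. Overlaps of calls were compared with the product of the list sizes over the genes tested, and for deletions that share wild type libraries also with 50 simulations of unchanged groups.

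The groups, contrasts, tests, thresholds, gene lists and all alternatives but 3 were fixed before the data were examined. So was the rule for named genes: the 10 largest rises and 10 largest falls per deletion and for the wild types, and 5 and 5 for the other contrasts and for shared calls. Each had an adjusted p under 0.05 and, except in differences between backgrounds and shared calls, all 3 libraries of one group above or below the 3 of the other. The rule further takes PIH1, TAH1, RVB1, RVB2, up to 4 members per list with the smallest adjusted p, and the chromosome neighbours of PIH1 and TAH1. Genes chosen otherwise are said to be so. The result of 1 gene that the rule names is not reported here.

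The alternatives were other pseudocounts, filters, scalings (TMM and quantile), library weights, a fit of only the libraries compared, the FPKM table, a replicate block, and leaving out each library in turn. After the data were seen 3 were added: a fit without the genes of chromosome XVI, and gene lists without PIH1 and TAH1, at the preset and at an estimated correlation. Count-based tests were planned and not run, since whole reads could not be recovered from the rounded values. The main test was tested on simulated data for the PIH1 deletion with tagged Rvb1: of genes changed 1.5-fold, 2-fold and 4-fold, 83.6%, 92.4% and 100% were called. There 5 unchanged genes were called (2.66% of calls), and 0 for wild types simulated without change (limma). These rates hold for simulated noise only.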

Results

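Messenger RNA was measured by sequencing in 18 libraries of budding yeast. Rvb1 and Rvb2 are paired AAA+ ATPases that work in the R2TP complex, with Pih1 and Tah1, and in the INO80 and SWR1 chromatin remodellers. The title of the series states that the Rvb1 and Rvb2 network was studied after loss of R2TP components. Per the labels there were 2 tagged backgrounds, each with wild type, PIH1 deletion and TAH1 deletion strains, and each of the 6 groups held 3 biological replicates. The normalized counts of a library summed to 4829249 to 5412654. Values given are mean normalized counts ± SD or log2 changes ± SE from limma, n = 3 libraries per group, and positions are those of sacCer3.

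On the first component of all tested genes (45.7% of the variance), the PIH1 deletion libraries with tagged Rvb2 lay apart from the other 15. On the second (19.0%), the TAH1 deletion libraries with tagged Rvb2 did. Replicate 2 of the Rvb1-tagged wild type stood apart from its own group. Its distance from the other 2 was 0.404 (root mean square, log2), against 0.155 to 0.306 in the other 17 libraries. It lay beside the Rvb1-tagged TAH1 deletion on these components, while its TAH1 count (185) and PIH1 count (162) were those of a wild type strain. Its HSP82 count was 699, against 3186 and 3177 in replicates 1 and 3, and its ARG4 count was 2094 against 795 and 712. HSP82 encodes HSP90, and ARG4 an enzyme of arginine synthesis. Both were chosen after their values were seen.

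**Figure D1:**
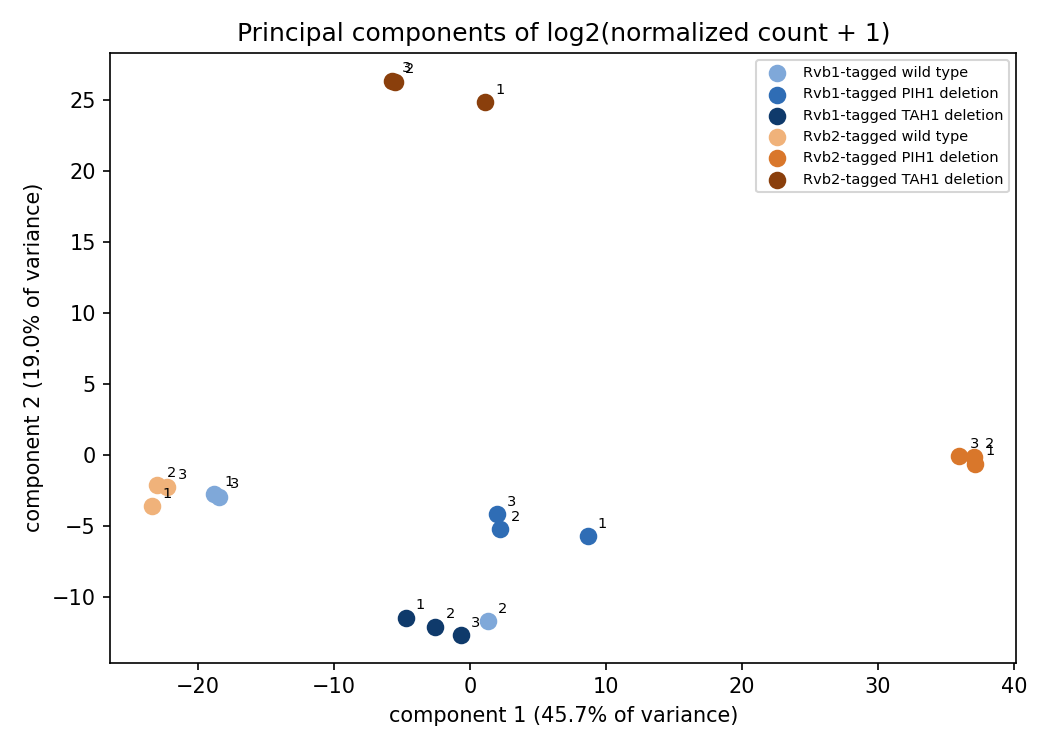
Each point is 1 of the 18 libraries, placed by its scores on the first (45.7% of the variance, x axis) and second (19.0%, y axis) principal components of log2(normalized count + 1); colours mark the 6 groups. The Rvb2-tagged PIH1 deletion lies at the right, the Rvb2-tagged TAH1 deletion at the top, and replicate 2 of the Rvb1-tagged wild type beside the Rvb1-tagged TAH1 deletion.

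The deleted genes were read first, as a check of the labels. PIH1 (YHR034C, protein-coding, chromosome VIII, 176965 to 177999) fell from 157 ± 9.24 to 6 ± 3 in the Rvb1-tagged PIH1 deletion, a log2 change of -4.59 ± 0.31 (adjusted p = 1.4e-08). With tagged Rvb2 it fell from 140 ± 17.9 to 3 ± 2, a log2 change of -5.27 ± 0.31 (adjusted p = 5.6e-10). In the TAH1 deletions PIH1 stood at 155 ± 9.02 and 161 ± 8.08. TAH1 (YCR060W, protein-coding, chromosome III, 224399 to 224734) fell from 175 ± 16.7 to 2.33 ± 0.577 in the Rvb1-tagged TAH1 deletion, a log2 change of -5.73 ± 0.15 (adjusted p = 2.4e-14). With tagged Rvb2 it went from 185 ± 14.2 to 0 in all 3 libraries, at least 61.6-fold lower against a floor of 3 normalized counts for the group mean. TAH1 measured 158 ± 21 and 226 ± 6.81 in the PIH1 deletions, log2 changes of -0.15 ± 0.15 (adjusted p = 0.45) and 0.29 ± 0.15 (adjusted p = 0.084).

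The transcript of the tagged gene fell in each of the 4 deletion strains, RVB1 where Rvb1 carried the tag and RVB2 where Rvb2 did. RVB1 (YDR190C, chromosome IV, 840604 to 841995) fell from 975 ± 53.3 to 657 ± 59.2 in the Rvb1-tagged PIH1 deletion and to 501 ± 8.89 in the Rvb1-tagged TAH1 deletion. The log2 changes were -0.57 ± 0.08 (adjusted p = 6.6e-05) and -0.96 ± 0.08 (adjusted p = 1e-06). With tagged Rvb2 it rose instead, from 903 ± 123 to 1647 ± 26.9 and 1639 ± 54.3, by 0.88 ± 0.08 (adjusted p = 9.4e-08) and 0.87 ± 0.08 (adjusted p = 1.7e-07). RVB2 (YPL235W, chromosome XVI, 103232 to 104647) fell in these strains from 882 ± 68.5 to 311 ± 12.1 and 521 ± 26.4, by -1.50 ± 0.07 (adjusted p = 3.2e-11) and -0.76 ± 0.07 (adjusted p = 9.1e-08). With tagged Rvb1 it stood at 916 ± 31 in the wild type, 1043 ± 65.2 in the PIH1 deletion (0.19 ± 0.07, adjusted p = 0.044) and 946 ± 60.7 in the TAH1 deletion (0.04 ± 0.07, adjusted p = 0.72). The first of these missed the threshold with TMM scaling (adjusted p = 0.0534) and quantile normalization (adjusted p = 0.310). It also missed it without wild type replicate 1 (adjusted p = 0.0962) or 3 (adjusted p = 0.139), and without PIH1 deletion replicate 2 (adjusted p = 0.177) or 3 (adjusted p = 0.0839).

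**Figure D2:**
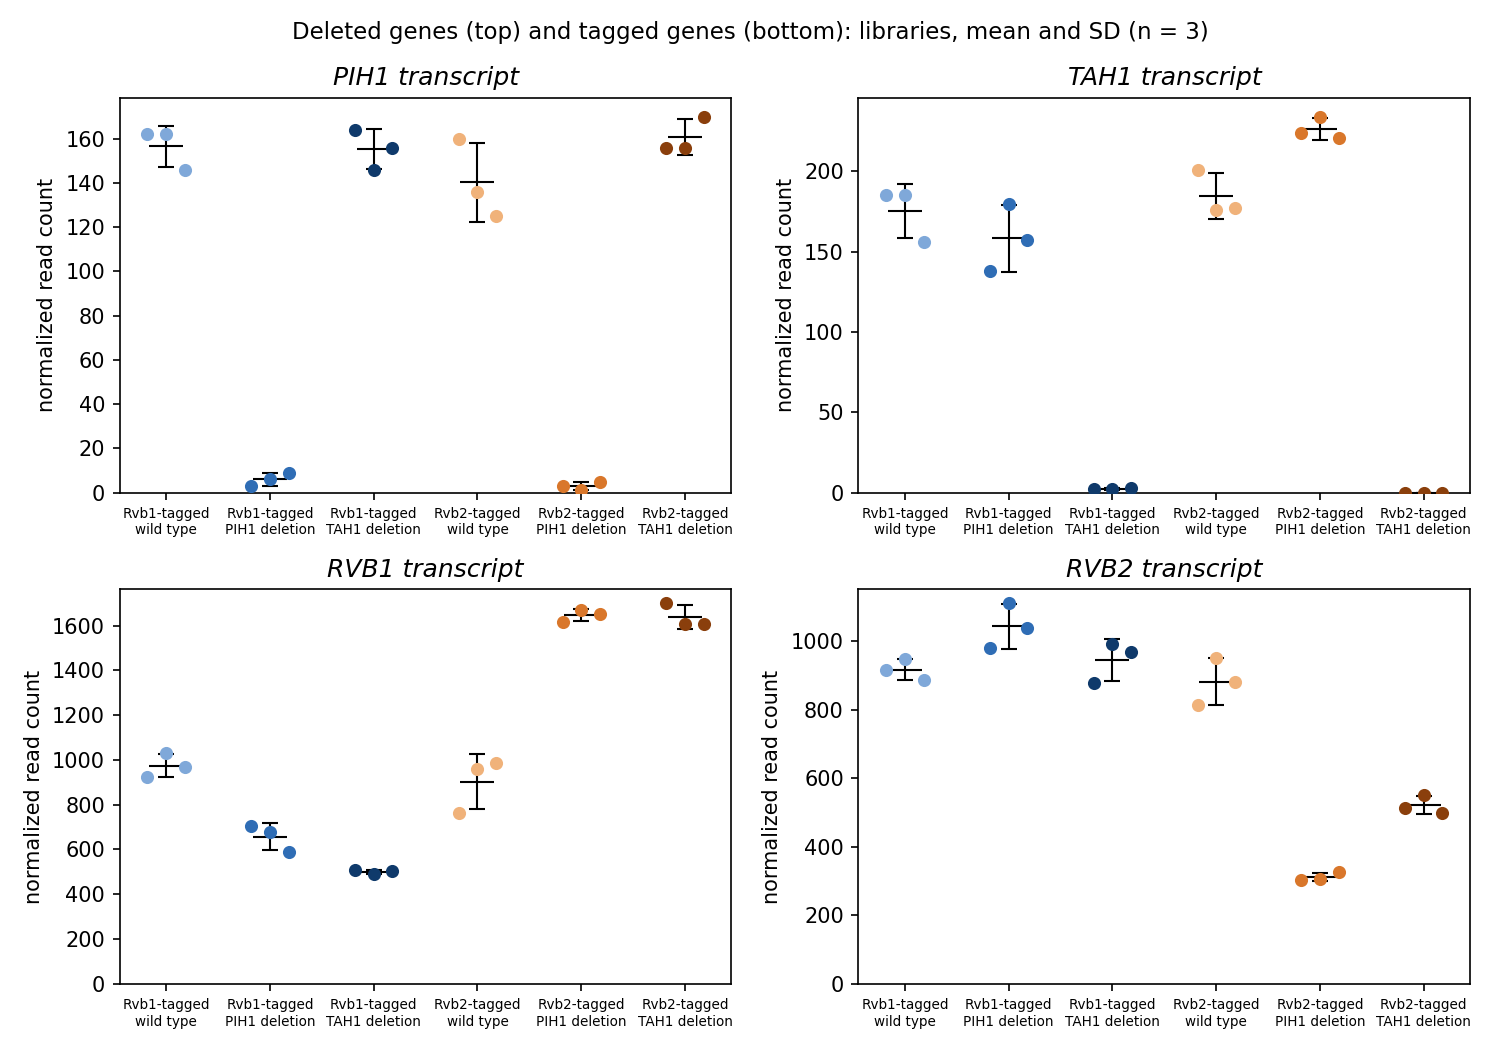
Normalized counts (y axes, from 0) of the deleted genes PIH1 and TAH1 and the tagged genes RVB1 and RVB2 in the 6 groups; points are libraries, bars the mean and error bars the SD (n = 3). RVB1 lies lower in the Rvb1-tagged deletions (657 and 501 against 975), and RVB2 in the Rvb2-tagged ones (311 and 521 against 882).

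Loss of PIH1 with tagged Rvb1 lowered genes of iron uptake, phosphate, glycolysis and purine synthesis, and raised ribosome biogenesis and proteasome genes, by camera at the preset correlation. With an estimated correlation none of these 6 lists passed (adjusted p = 0.076 to 0.53). IMD2, which encodes an IMP dehydrogenase of guanine nucleotide synthesis (YHR216W, chromosome VIII, 554396 to 555967), fell most after PIH1 itself, from 537 ± 122 to 55.3 ± 9.02 (-3.24 ± 0.13, adjusted p = 1.1e-11). HSP12, a small stress protein of membranes (YFL014W, chromosome VI, 107256 to 107585), rose most, from 277 ± 104 to 2956 ± 1130 (3.41 ± 0.49, adjusted p = 5.5e-05). In all, 2211 of 5825 genes passed limma's threshold, 1119 higher and 1092 lower. Of these, 18 rose and 133 fell more than 2-fold.

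Among the other large rises were U3 snoRNA from snR17a (2.08 ± 0.32), the U2 snRNA LSR1 (1.25 ± 0.20), snR57 (1.22 ± 0.36) and the 21S mitochondrial rRNA (21S_rRNA, 3.33 ± 0.55), none of which has a long poly(A) tail. CTT1, the cytosolic catalase, rose by 1.58 ± 0.41 (adjusted p = 0.0605 with only the libraries compared), and CCW22, close in sequence to CCW12 and so of uncertain assignment, by 1.26 ± 0.12. GAP1, the general amino acid permease (1.43 ± 0.45, adjusted p = 0.019), ALD4, a mitochondrial aldehyde dehydrogenase (1.26 ± 0.40, adjusted p = 0.019), and SPI1, a cell wall protein (1.29 ± 0.47, adjusted p = 0.039), rose less securely. Without PIH1 deletion replicate 2 their adjusted p values were 0.0976, 0.0825 and 0.140, and without replicate 3 they were 0.0638, 0.0590 and 0.113. With only the libraries compared ALD4 and SPI1 were at adjusted p = 0.0678 and 0.0744, and SPI1 at 0.0529 with the FPKM table. ALD4 and SPI1 also missed the threshold without wild type replicate 2 (adjusted p = 0.0641 and 0.124), and snR57 without wild type replicate 1 (adjusted p = 0.0540) or PIH1 deletion replicate 2 (adjusted p = 0.0578). Large falls were those of CIS1 (-3.07 ± 0.26), STE3, the a-factor receptor of alpha cells (-2.93 ± 0.37), the cell wall protein TIR1 (-2.64 ± 0.14), the acid phosphatase PHO12 (-2.56 ± 0.23), and NFG1 (-2.24 ± 0.16). BNA2, of NAD synthesis, overlaps YJR079W and is uncertain at -2.26 ± 0.36. PHO12 shares sequence with other acid phosphatase genes. The neighbours of PIH1 both rose, YHR033W by 1.05 ± 0.13 and NEL1 by 0.73 ± 0.15.

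Of 26 iron regulon genes 19 fell and 1 rose, 20 and 1 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 3.7e-11; adjusted p = 0.076 with an estimated correlation). FIT3 (-2.25 ± 0.08) and FIT2 (-2.73 ± 0.16), cell wall proteins that retain siderophore iron, ARN1 (-1.16 ± 0.08), a siderophore transporter, and TIS11 (-2.55 ± 0.14), which acts on mRNA in iron shortage, were among them. Of 18 phosphate genes 13 fell, and 13 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 2.0e-07; adjusted p = 0.16 with an estimated correlation). They include the vacuolar polyphosphate gene VTC3 (-1.05 ± 0.08), the acid phosphatase PHO5 (-1.62 ± 0.17) and the transporter PHO84 (-1.40 ± 0.11), whose locus overlaps YNCM0001W. In glycolysis 14 of 17 fell, 15 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 9.4e-08; adjusted p = 0.32 with an estimated correlation). Hexokinase HXK2 fell by -0.94 ± 0.07 and TDH2, a dehydrogenase close in sequence to TDH1 and TDH3, by -2.07 ± 0.19. Of 20 purine and one-carbon genes 14 fell, 15 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 9.9e-10; adjusted p = 0.21 with an estimated correlation). ADE17 fell by -1.97 ± 0.17 and SHM2 by -1.19 ± 0.08.

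Ribosome biogenesis genes rose, 47 of 66, and 62 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 1.5e-11; adjusted p = 0.53 with an estimated correlation). UTP9 (0.71 ± 0.13) and IMP4 (0.80 ± 0.17), of the small subunit processome, were among them. Proteasome genes rose in 30 of 33 cases and fell in 1, or 31 and 1 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 2.9e-11; adjusted p = 0.32 with an estimated correlation). The lid subunit RPN9 rose by 0.57 ± 0.06. Of 12 RNA polymerase II subunits 10 rose, and 10 adjusted over the list alone, such as RPB9 (0.46 ± 0.07; camera adjusted p = 0.00017; adjusted p = 0.21 with an estimated correlation). Of 14 snoRNP genes 5 rose, 7 adjusted over the list alone (camera adjusted p = 0.0059; adjusted p = 0.61 with an estimated correlation), among them RSA1 (0.67 ± 0.14), a snoRNP assembly factor. The snoRNP call ended without wild type replicate 3 (adjusted p = 0.0528). Ergosterol genes fell in 12 of 24 cases and rose in 3, the same numbers adjusted over the list alone (median -0.14, camera adjusted p = 0.027; adjusted p = 0.46 with an estimated correlation). Subtelomeric genes fell in 66 of 257 cases and rose in 31, the same numbers adjusted over the list alone (median -0.11, camera adjusted p = 0.012; adjusted p = 0.37 with an estimated correlation). Alpha-cell and meiosis genes, markers of other yeast cell types, fell in 9 of 25 cases, and 9 adjusted over the list alone, such as SPS4 (-1.70 ± 0.21; camera adjusted p = 0.037; adjusted p = 0.35 with an estimated correlation).

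In the respiratory list 14 of 43 genes rose and 3 fell, the same numbers adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.011; adjusted p = 0.78 with an estimated correlation). Without wild type replicate 2 this call ended (median 0.04, adjusted p = 0.97), as did those of the ergosterol list (adjusted p = 0.14) and the alpha-cell list (adjusted p = 0.11). Without PIH1 deletion replicate 3 the ergosterol and alpha-cell lists also missed the threshold (adjusted p = 0.0511 and 0.0501), and the alpha-cell list without replicate 1 (adjusted p = 0.0554). With library weights the respiratory, ergosterol and alpha-cell lists missed it too (adjusted p = 0.554, 0.0841 and 0.103). With quantile normalization the respiratory, subtelomeric and alpha-cell lists did (adjusted p = 0.258, 0.110 and 0.306), and at a mean count of at least 50 the alpha-cell list did (adjusted p = 0.665), as it did without the genes of chromosome XVI (adjusted p = 0.0747). The heat shock list, with 6 of 22 higher and 3 lower (the same numbers adjusted over the list alone; median 0.15, camera adjusted p = 0.67), turned to a median of -0.15 without wild type replicate 2 (adjusted p = 0.033). The general stress list, with 3 of 28 higher and 2 lower (2 and 2 adjusted over the list alone; median 0.03, camera adjusted p = 0.83), turned to -0.49 without that replicate (adjusted p = 0.012). Amino acid genes, with 5 of 43 higher and 5 lower (1 and 4 adjusted over the list alone; median 0.04, camera adjusted p = 0.80), had a median of 0.27 without it (adjusted p = 0.0017). A fit of only these 6 libraries called 1277 genes.

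Cytosolic ribosomal protein genes as a list did not pass camera, with 8 of 137 higher and 13 lower (5 and 10 adjusted over the list alone; adjusted p = 0.26). Single members moved far: RPL9B fell from 3142 ± 111 to 959 ± 46.8 (-1.71 ± 0.06), RPL8A from 5428 ± 755 to 1261 ± 139 (-2.10 ± 0.09) and RPL7B by -1.72 ± 0.13. Each has a paralog close in sequence. TRA1, a PIKK-family subunit of histone acetyltransferases, rose by 0.79 ± 0.08 in a PIKK list of 9 with 3 higher, and 3 adjusted over the list alone (camera adjusted p = 0.14). The other lists that did not pass camera were R2TP and HSP90, INO80, SWR1, glucose-repressed genes, phospholipid synthesis, mating, methionine, amino acid biosynthesis, histones, DNA damage and cell wall, with camera adjusted p values of 0.10 to 0.94.

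In the TAH1 deletion with tagged Rvb1, phosphate genes rose and iron genes fell. PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII, 24037 to 25800), rose from 6296 ± 1591 to 16944 ± 675 (1.46 ± 0.11, adjusted p = 1.5e-07). PDR5, a drug efflux pump (YOR153W, chromosome XV, 619840 to 624375), fell from 13225 ± 830 to 3200 ± 75.1 (-2.05 ± 0.08, adjusted p = 6.4e-12). With limma, 627 genes passed, 366 higher and 261 lower, 27 and 33 of them more than 2-fold. Quantile normalization gave 267 higher and 320 lower.

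Among the largest rises were those of PHO89, a sodium-phosphate transporter (2.61 ± 0.50), HSP12 (2.58 ± 0.49), snR17a (1.69 ± 0.32) and HXT4, a glucose transporter (1.42 ± 0.19). ARG4 (1.83 ± 0.29) and ARG1 (1.67 ± 0.38) of arginine synthesis, ARO5 (1.58 ± 0.29) and ATG41 (1.50 ± 0.30) rose too. With only the libraries compared the adjusted p was 0.101 for PHO89, 0.131 for HSP12, 0.0817 for ARG4, 0.153 for ARG1, 0.102 for ARO5 and 0.123 for ATG41. ARG1 missed the threshold without wild type replicate 1 (adjusted p = 0.0534) or 3 (adjusted p = 0.0578), and changed by 2.30 without wild type replicate 2. Without TAH1 deletion replicate 2 PHO89 changed by 3.40 and HSP12 by 3.31, and without replicate 1 HSP12 by 1.83. The largest falls were those of CIS1 (-2.46 ± 0.26), YNL018C (-2.17 ± 0.47), FIT2 (-2.08 ± 0.16), FIT3 (-2.04 ± 0.08), STE3 (-1.88 ± 0.37), TMA10 (-1.85 ± 0.40), PES4 (-1.78 ± 0.41), HUG1, an inhibitor of ribonucleotide reductase (-1.72 ± 0.29), and the efflux pump PDR15 (-1.66 ± 0.16). With only the libraries compared TMA10, PES4 and HUG1 missed the threshold (adjusted p = 0.123, 0.0666 and 0.0802). Of the neighbours of TAH1, YIH1 changed by -0.41 ± 0.11 (adjusted p = 0.020) and TVS1 by -0.73 ± 0.21 (adjusted p = 0.035). YIH1 missed the threshold without TAH1 deletion replicate 1 (adjusted p = 0.0787) or 3 (adjusted p = 0.0529), and with only the libraries compared (adjusted p = 0.0906). TVS1 missed it without wild type replicate 1 (adjusted p = 0.184) or 3 (adjusted p = 0.178), or TAH1 deletion replicate 2 (adjusted p = 0.0603) or 3 (adjusted p = 0.148). It missed it with only the libraries compared too (adjusted p = 0.254), with the FPKM table (adjusted p = 0.0531) and with a replicate block (adjusted p = 0.0545).

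Of 18 phosphate genes 14 rose, or 16 with 1 lower adjusted over the list alone, with a median of 0.84 (camera adjusted p = 3.9e-17; adjusted p = 0.043 with an estimated correlation). VTC3 (1.09 ± 0.08), VTC4 (0.82 ± 0.06) and the vacuolar phosphatase PHO8 (0.86 ± 0.06) were among them. Amino acid synthesis genes of the Gcn4 type rose in 36 of 43 cases, 41 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 3.6e-27; adjusted p = 0.21 with an estimated correlation), such as LEU4 (0.91 ± 0.09) and HIS3 (0.73 ± 0.09). In wild type replicate 2, with TAH1 at 185, ARG4 stood at 2094 and ARG1 at 1371. Replicates 1 and 3 had 795 and 712 for ARG4, and 387 and 362 for ARG1. Higher counts of these genes were thus not limited to libraries without TAH1. Methionine genes rose in 5 of 22 cases, 11 adjusted over the list alone (median 0.42, camera adjusted p = 3.5e-06; adjusted p = 0.42 with an estimated correlation), such as MET16 (0.94 ± 0.17). Purine genes rose in 11 of 20 cases, 15 adjusted over the list alone (median 0.33, camera adjusted p = 2.2e-06; adjusted p = 0.38 with an estimated correlation). HIS4 (1.15 ± 0.21) and HIS1 (0.56 ± 0.09), counted here and in the amino acid list, were 2 of them. Mating genes rose in 11 of 24 cases, or 16 with 1 lower adjusted over the list alone (median 0.29, camera adjusted p = 4.0e-08; adjusted p = 0.076 with an estimated correlation). The agglutinin genes AGA2 and AGA1 rose by 0.76 ± 0.08 and 0.72 ± 0.08.

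Iron regulon genes fell in 13 of 26 cases, 14 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 2.1e-14; adjusted p = 0.043 with an estimated correlation). The siderophore transporter ENB1 fell by -0.98 ± 0.10. Of 13 R2TP and HSP90 genes 4 fell, TAH1 and RVB1 among them, and 8 adjusted over the list alone (median -0.29, camera adjusted p = 6.4e-07; adjusted p = 0.15 with an estimated correlation). Without PIH1 and TAH1 in this list, a test chosen after the data were seen, the other 11 kept a median of -0.29 (camera adjusted p = 4.2e-05; adjusted p = 0.28 with an estimated correlation). The cochaperone STI1 fell by -0.75 ± 0.16 and HSC82, the constitutive HSP90, by -0.42 ± 0.10. Heat shock genes fell in 8 of 22 cases, 18 adjusted over the list alone (median -0.47, camera adjusted p = 6.7e-09; adjusted p = 0.39 with an estimated correlation), such as the mitochondrial chaperonins HSP60 (-0.71 ± 0.10) and HSP10 (-0.58 ± 0.07). HSP82, chosen after its values were seen, stood at 777 to 1024 in the TAH1 deletion, but also at 699 in wild type replicate 2, which keeps TAH1. DNA damage genes fell in 6 of 17 cases, 7 adjusted over the list alone (camera adjusted p = 0.00062; adjusted p = 0.15 with an estimated correlation), such as MAG1 (-0.67 ± 0.12). In glycolysis 4 of 17 fell, and 4 adjusted over the list alone, HXK2 by -0.63 ± 0.07 (camera adjusted p = 0.00082; adjusted p = 0.48 with an estimated correlation).

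Ribosome biogenesis genes rose in 4 of 66 cases and in 59 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 1.5e-14; adjusted p = 0.52 with an estimated correlation). HAS1, an RNA helicase, rose by 0.63 ± 0.18. In the snoRNP list of 14, RSA1 rose (0.45 ± 0.14), and limma adjusted over the list alone gave 0 calls with 8 at an unadjusted p under 0.05 (median 0.27, camera adjusted p = 0.0027; adjusted p = 0.59 with an estimated correlation). This call ended without wild type replicate 3 (adjusted p = 0.0660). Respiratory genes rose in 17 of 43 cases, 18 adjusted over the list alone (median 0.19, camera adjusted p = 1.0e-06; adjusted p = 0.53 with an estimated correlation), such as COX13 (0.43 ± 0.07). Alpha-cell and meiosis genes fell in 2 of 25 cases, STE3 and DIT1 (-1.13 ± 0.23), and in 2 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.24 with an estimated correlation). The respiratory and alpha-cell calls ended without wild type replicate 2 (adjusted p = 0.41 and 0.11), and the latter without TAH1 deletion replicate 3 (adjusted p = 0.0536). Both missed the threshold with library weights (adjusted p = 0.204 and 0.0807), and the alpha-cell list at a mean count of at least 50 (adjusted p = 0.204) and with quantile normalization (adjusted p = 0.258). The general stress list, with 1 of 28 higher and 3 lower (the same numbers adjusted over the list alone, median -0.31, camera adjusted p = 0.12), had a median of -0.79 without wild type replicate 2 (adjusted p = 2.0e-06). The proteasome list passed camera at a median of -0.06 (adjusted p = 0.0041; adjusted p = 0.60 with an estimated correlation), with 0 single genes past limma's threshold and 2 of 33 at an unadjusted p under 0.05. In the INO80, SWR1 and PIKK lists limma called 0 genes, with 2, 1 and 2 at an unadjusted p under 0.05. It called 0 of 137 ribosomal protein genes too, with 4 at an unadjusted p under 0.05 (median 0.05, camera adjusted p = 0.095), and without wild type replicate 2 that list had a median of 0.13 (adjusted p = 0.00015).

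The count of this contrast rested on single wild type libraries. It was 1827 without wild type replicate 2, 314 without replicate 1 and 296 without replicate 3, and 382, 405 and 401 without TAH1 deletion replicates 1, 2 and 3. A fit of only these 6 libraries called 74 genes, and library weights gave 2368.

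Loss of PIH1 with tagged Rvb2 changed the most genes: stress, heat shock, glycolytic and respiratory genes fell, and ribosome biogenesis genes and snoRNAs rose. The 5 list calls among these were made at the preset correlation, and none passed with an estimated correlation (adjusted p = 0.44 to 0.59). HXK1, a hexokinase of cells short of glucose (YFR053C, chromosome VI, 253592 to 255049), fell from 6432 ± 991 to 141 ± 9.29 (-5.49 ± 0.36, adjusted p = 1.3e-09). HSP82, the inducible HSP90 (YPL240C, chromosome XVI, 96496 to 98625), fell from 3494 ± 98.2 to 224 ± 12.5 (-3.96 ± 0.36, adjusted p = 6.1e-08). U3 snoRNA from snR17a (chromosome XV, 780107 to 780596) rose from 10 ± 6.56 to 367 ± 33.2 (5.25 ± 0.32, adjusted p = 6.4e-10). With limma, 4054 genes passed, 2053 higher and 2001 lower, 480 and 463 of them more than 2-fold.

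The 10 largest rises were those of RNAs without a poly(A) tail: the snoRNAs snR17a, snR30 (4.67 ± 0.16), snR8 (3.87 ± 0.25), snR37 (3.69 ± 0.30), snR17b (3.51 ± 0.27), snR86 (3.21 ± 0.14), snR13 (3.16 ± 0.48), snR34 (3.11 ± 0.32) and snR35 (3.03 ± 0.28), and SCR1, the RNA of the signal recognition particle (2.95 ± 0.26). Of 24 tested box H/ACA snoRNAs, which guide pseudouridylation, 21 rose and 1 fell, with a median of 2.09. Of 22 box C/D snoRNAs, which guide methylation, 15 rose and 1 fell, with a median of 1.26. Of 6 other RNAs without a tail 5 rose, with a median of 1.88. These classes were drawn up after the values were seen. In the Rvb1-tagged PIH1 deletion the medians were 0.21, 0.11 and 0.77. Beside HXK1 and HSP82 the large falls were those of TDH1 (-5.19 ± 0.86), close to TDH2 and TDH3 in sequence, SOL4 of the pentose phosphate pathway (-3.93 ± 0.79), FIG1 of mating (-3.89 ± 0.51), PHO84 (-3.77 ± 0.11), HXT7, a hexose transporter near identical to HXT6 (-3.76 ± 0.27), TSL1 of trehalose synthesis (-3.69 ± 0.47) and the glucokinase-like EMI2 (-3.66 ± 0.31). Glucokinase GLK1, whose locus overlaps YCL042W, was at -4.08 ± 0.41. The PIH1 neighbours rose, YHR033W by 1.34 ± 0.13 and NEL1 by 1.31 ± 0.15.

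General stress genes fell in 22 of 28 cases, and 22 adjusted over the list alone, with a median of -2.24 (camera adjusted p = 3.7e-05; adjusted p = 0.59 with an estimated correlation), such as PNC1 (-3.23 ± 0.34) of NAD salvage. Heat shock genes fell in 18 of 22 cases and rose in 1, 19 and 1 adjusted over the list alone, with a median of -1.43 (camera adjusted p = 1.5e-06; adjusted p = 0.46 with an estimated correlation). The HSP70 gene SSA1 fell by -3.23 ± 0.22 and HSP60 by -2.03 ± 0.10. R2TP and HSP90 genes fell in 10 of 13 cases and rose in 1, the same numbers adjusted over the list alone (median -1.08, camera adjusted p = 0.0015; adjusted p = 0.35 with an estimated correlation), among them HSC82, from 15199 ± 90.1 to 5638 ± 65.7 (-1.43 ± 0.10), and the kinase cochaperone CDC37 (-0.80 ± 0.06). Without PIH1 and TAH1 in that list the camera adjusted p was 0.0017 (adjusted p = 0.39 with an estimated correlation). Respiratory genes fell in 39 of 43 cases, and 39 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 2.4e-10; adjusted p = 0.46 with an estimated correlation), such as LSC2 (-1.73 ± 0.12). In glycolysis 15 of 17 fell and 1 rose, the same numbers adjusted over the list alone (median -0.74, camera adjusted p = 5.1e-05; adjusted p = 0.44 with an estimated correlation). PGK1 fell by -1.88 ± 0.09.

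Phosphate genes fell in 14 of 18 cases and rose in 2, the same numbers adjusted over the list alone (median -0.61, camera adjusted p = 0.00051; adjusted p = 0.37 with an estimated correlation), such as VTC3 (-2.19 ± 0.08). Purine genes fell in 14 of 20 cases and rose in 3, 14 and 4 adjusted over the list alone (camera adjusted p = 0.0097; adjusted p = 0.55 with an estimated correlation). ADE17 fell by -3.16 ± 0.17. Proteasome genes fell in 29 of 33 cases, and 29 adjusted over the list alone (median -0.39, camera adjusted p = 9.3e-07; adjusted p = 0.46 with an estimated correlation), such as RPT2 (-0.65 ± 0.06). Histone genes fell in 7 of 10 cases, and 7 adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.58 with an estimated correlation), such as the linker histone gene HHO1 (-0.83 ± 0.08). Without the genes of chromosome XVI the histone list missed the threshold (adjusted p = 0.0575). DNA damage genes fell in 11 of 17 cases and rose in 3, the same numbers adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.39 with an estimated correlation). The checkpoint kinase gene DUN1 fell by -1.17 ± 0.09. That list missed the threshold at a mean count of at least 50 (adjusted p = 0.165), with quantile normalization (adjusted p = 0.0603) and with only the libraries compared (adjusted p = 0.0579). It also missed it without wild type replicate 2 (adjusted p = 0.05003) or 3 (adjusted p = 0.0536), or PIH1 deletion replicate 3 (adjusted p = 0.0503).

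All 66 ribosome biogenesis genes rose, adjusted over the list alone too, with a median of 1.31 (camera adjusted p = 1.7e-17; adjusted p = 0.47 with an estimated correlation). UTP20 rose by 2.02 ± 0.19 and PWP2 by 1.61 ± 0.15. All 14 snoRNP protein genes rose, adjusted over the list alone too, with a median of 0.95 (camera adjusted p = 3.1e-05; adjusted p = 0.48 with an estimated correlation), such as NOP1 (1.15 ± 0.12), the methyltransferase of box C/D particles, and NAF1 (1.57 ± 0.17), an assembly factor of box H/ACA particles. PIKK genes rose in 8 of 9 cases, and 8 adjusted over the list alone (median 0.49, camera adjusted p = 0.020; adjusted p = 0.21 with an estimated correlation). TRA1 rose by 1.11 ± 0.08. Alpha-cell and meiosis genes rose in 18 of 25 cases and fell in 3, the same numbers adjusted over the list alone (median 0.66, camera adjusted p = 0.027; adjusted p = 0.32 with an estimated correlation), among them NDT80 (1.64 ± 0.11), a meiotic regulator, while STE3 fell (-2.01 ± 0.37). That call ended with no filter on low counts (adjusted p = 0.0589), at a mean count of at least 50 (median 0.38, adjusted p = 0.128) and with quantile normalization (adjusted p = 0.0912). RPL8A fell to 597 ± 16.6 from 5184 ± 482 (-3.11 ± 0.09), and RPS9A by -1.65 ± 0.07, while RPL18B rose by 1.46 ± 0.07. The ribosomal protein list, with 16 of 137 higher and 14 lower (10 and 12 adjusted over the list alone), did not pass camera (adjusted p = 0.94). Nor did the RNA polymerase II list, with 8 of 12 higher and 1 lower (the same numbers adjusted over the list alone; adjusted p = 0.051), or the glucose-repressed list, with 13 of 22 higher and 4 lower (the same numbers adjusted over the list alone; adjusted p = 0.16).

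In the TAH1 deletion with tagged Rvb2, phosphate, purine and ribosomal protein genes fell, and the genes of chromosome XVI rose together. The 3 list calls were made with camera at the preset correlation, and none passed with an estimated correlation (adjusted p = 0.16 to 0.53). PHO84 fell from 5923 ± 295 to 318 ± 6.51 (-4.21 ± 0.11, adjusted p = 1.2e-14), and SPL2, a small protein of the phosphate pathway (YHR136C, chromosome VIII, 374654 to 375100), from 161 ± 21.4 to 5.67 ± 3.79 (-4.74 ± 0.32, adjusted p = 1.7e-09). TDA6 (YPR157W, chromosome XVI, 841266 to 842669) rose most, from 107 ± 2.31 to 1158 ± 41.5 (3.43 ± 0.09, adjusted p = 8.3e-15). With limma, 2589 genes passed, 1389 higher and 1200 lower, 251 and 75 of them more than 2-fold. Quantile normalization gave 1180 higher and 1533 lower.

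Of 450 tested genes on chromosome XVI, 419 rose and 6 fell, and their median was 0.94 above that of all genes, or 1.92-fold. The largest shift of another chromosome was 0.14. In the 3 TAH1 deletion libraries the chromosome median, relative to the wild type, was 0.933 to 0.952. Off chromosome XVI, 970 genes rose and 1194 fell. All 3 TAH1 deletion libraries carried the shift, so these changes cannot be divided between the loss of TAH1 and the shift of chromosome XVI. Of the largest rises, TDA6, GUP2 (2.63 ± 0.18), RRG8 (2.57 ± 0.47), the polyamine exporter gene TPO3 (2.50 ± 0.10), HOB2 (2.27 ± 0.06), snR17b (2.08 ± 0.27) and RMI1 of the Sgs1 complex (2.08 ± 0.10) lie on it. The others were YGR139W (3.17 ± 0.59), snR17a (2.44 ± 0.32) and BSC1 (2.22 ± 0.52). Without wild type replicate 1 YGR139W rose by 2.47 and RRG8 by 1.73, and without wild type replicate 3 YGR139W rose by 4.06. RVB2, on the same chromosome, lay -1.72 from the chromosome median.

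**Figure D3:**
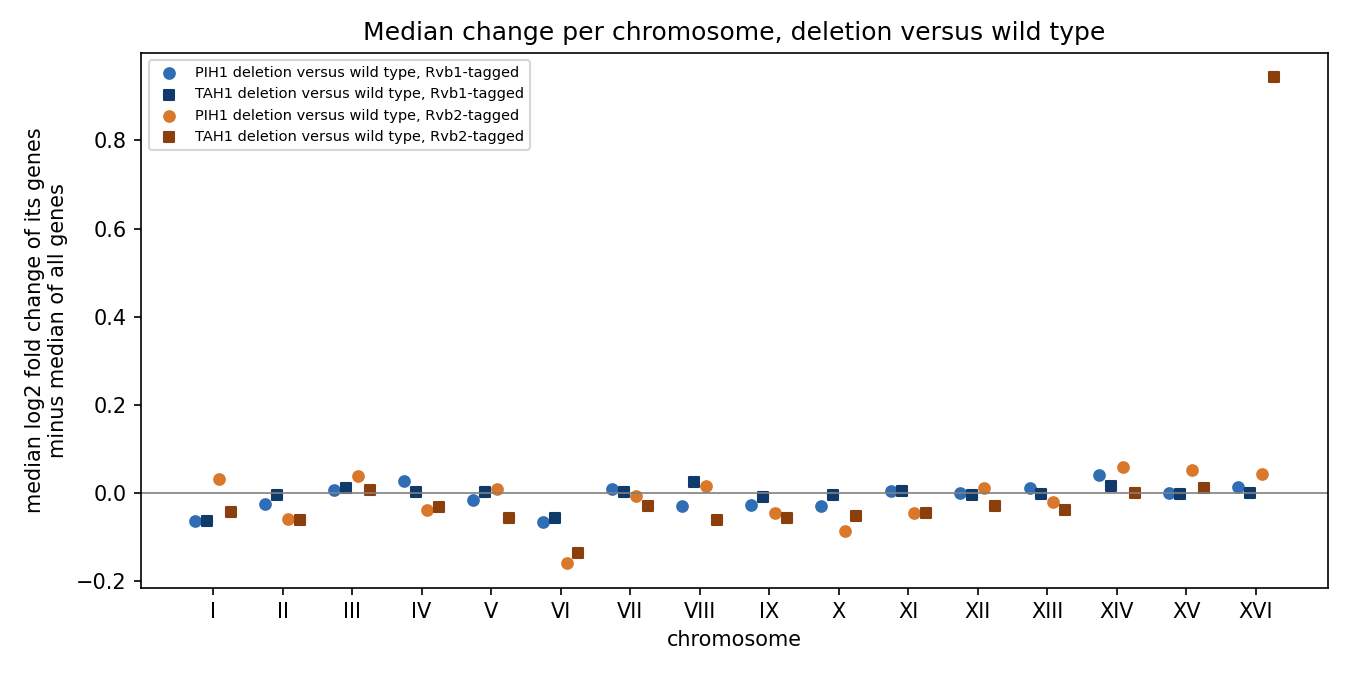
Median log2 change of the tested genes on each of the 16 chromosomes (x axis) minus the median of all genes (y axis) in the 4 deletion against wild type comparisons, 1 marker per comparison. Chromosome XVI stands at 0.94 in the Rvb2-tagged TAH1 deletion.

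The further large falls were those of MDH2, the cytosolic malate dehydrogenase (-3.21 ± 0.20), URA1 of pyrimidine synthesis (-2.50 ± 0.15), BAT2, a branched-chain aminotransferase (-2.44 ± 0.12), FIG1 (-2.42 ± 0.51), TMA10 (-2.29 ± 0.40), PHO12 (-2.14 ± 0.23) and CIS1 (-2.01 ± 0.26). TDH1 fell by -2.44 ± 0.86 (adjusted p = 0.029), a call lost without TAH1 deletion replicate 1 (-1.57, adjusted p = 0.168) or without wild type replicate 1, 2 or 3 (adjusted p = 0.0674, 0.0623 and 0.0589). Of the TAH1 neighbours YIH1 fell by -0.48 ± 0.11 and TVS1 changed by -0.28 ± 0.21 (adjusted p = 0.30).

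Phosphate genes fell in 13 of 18 cases and rose in 2, the same numbers adjusted over the list alone, with a median of -0.74 (camera adjusted p = 1.4e-07; adjusted p = 0.16 with an estimated correlation). VTC4 fell by -1.46 ± 0.06. Ribosomal protein genes fell in 104 of 137 cases and rose in 9, 107 and 10 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 1.1e-14; adjusted p = 0.53 with an estimated correlation). RPL9B fell by -1.04 ± 0.06 and RPL8A by -1.51 ± 0.09, while RPL5, on chromosome XVI, rose by 0.93 ± 0.09. Purine genes fell in 14 of 20 cases, and 14 adjusted over the list alone (median -0.41, camera adjusted p = 9.5e-06; adjusted p = 0.39 with an estimated correlation), such as IMD2 (-1.43 ± 0.13). Iron genes fell in 13 of 26 cases and rose in 1, 14 and 2 adjusted over the list alone (camera adjusted p = 0.0074; adjusted p = 0.42 with an estimated correlation): FIT2 fell by -1.89 ± 0.16, and ISU1, on chromosome XVI, rose by 1.46 ± 0.07. Mating genes fell in 11 of 24 cases and rose in 4, the same numbers adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.39 with an estimated correlation). AGA1 fell by -1.27 ± 0.08.

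In glycolysis 11 of 17 genes fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.52 with an estimated correlation), HXK2 by -0.84 ± 0.07. Respiratory genes fell in 19 of 43 cases and rose in 4, 20 and 4 adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.71 with an estimated correlation): IDH1 fell by -1.06 ± 0.12, and FUM1, on chromosome XVI, rose by 0.90 ± 0.05. Phospholipid synthesis genes fell in 8 of 18 cases and rose in 3, the same numbers adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.39 with an estimated correlation), such as the methyltransferase genes CHO2 (-1.22 ± 0.08) and OPI3 (-1.41 ± 0.13). That call ended with quantile normalization (adjusted p = 0.0603). Ribosome biogenesis genes rose in 55 of 66 cases, 61 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 2.0e-09; adjusted p = 0.59 with an estimated correlation). The 4 with the smallest p, among them TIF6 (1.34 ± 0.09) and NOG1 (1.46 ± 0.16), lie on chromosome XVI. In the snoRNP list 9 of 14 rose, 10 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.66 with an estimated correlation), and in the PIKK list 5 of 9, 6 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.17 with an estimated correlation). RSA1 (1.30 ± 0.14) and ASA1 (1.29 ± 0.08) lie on chromosome XVI, while TRA1 (0.87 ± 0.08) lies on chromosome VIII. In the cell wall list 13 of 27 rose and 7 fell, 14 and 7 adjusted over the list alone, and it passed camera only without the genes of chromosome XVI (adjusted p = 0.21, and 0.026 without them).

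**Figure D4:**
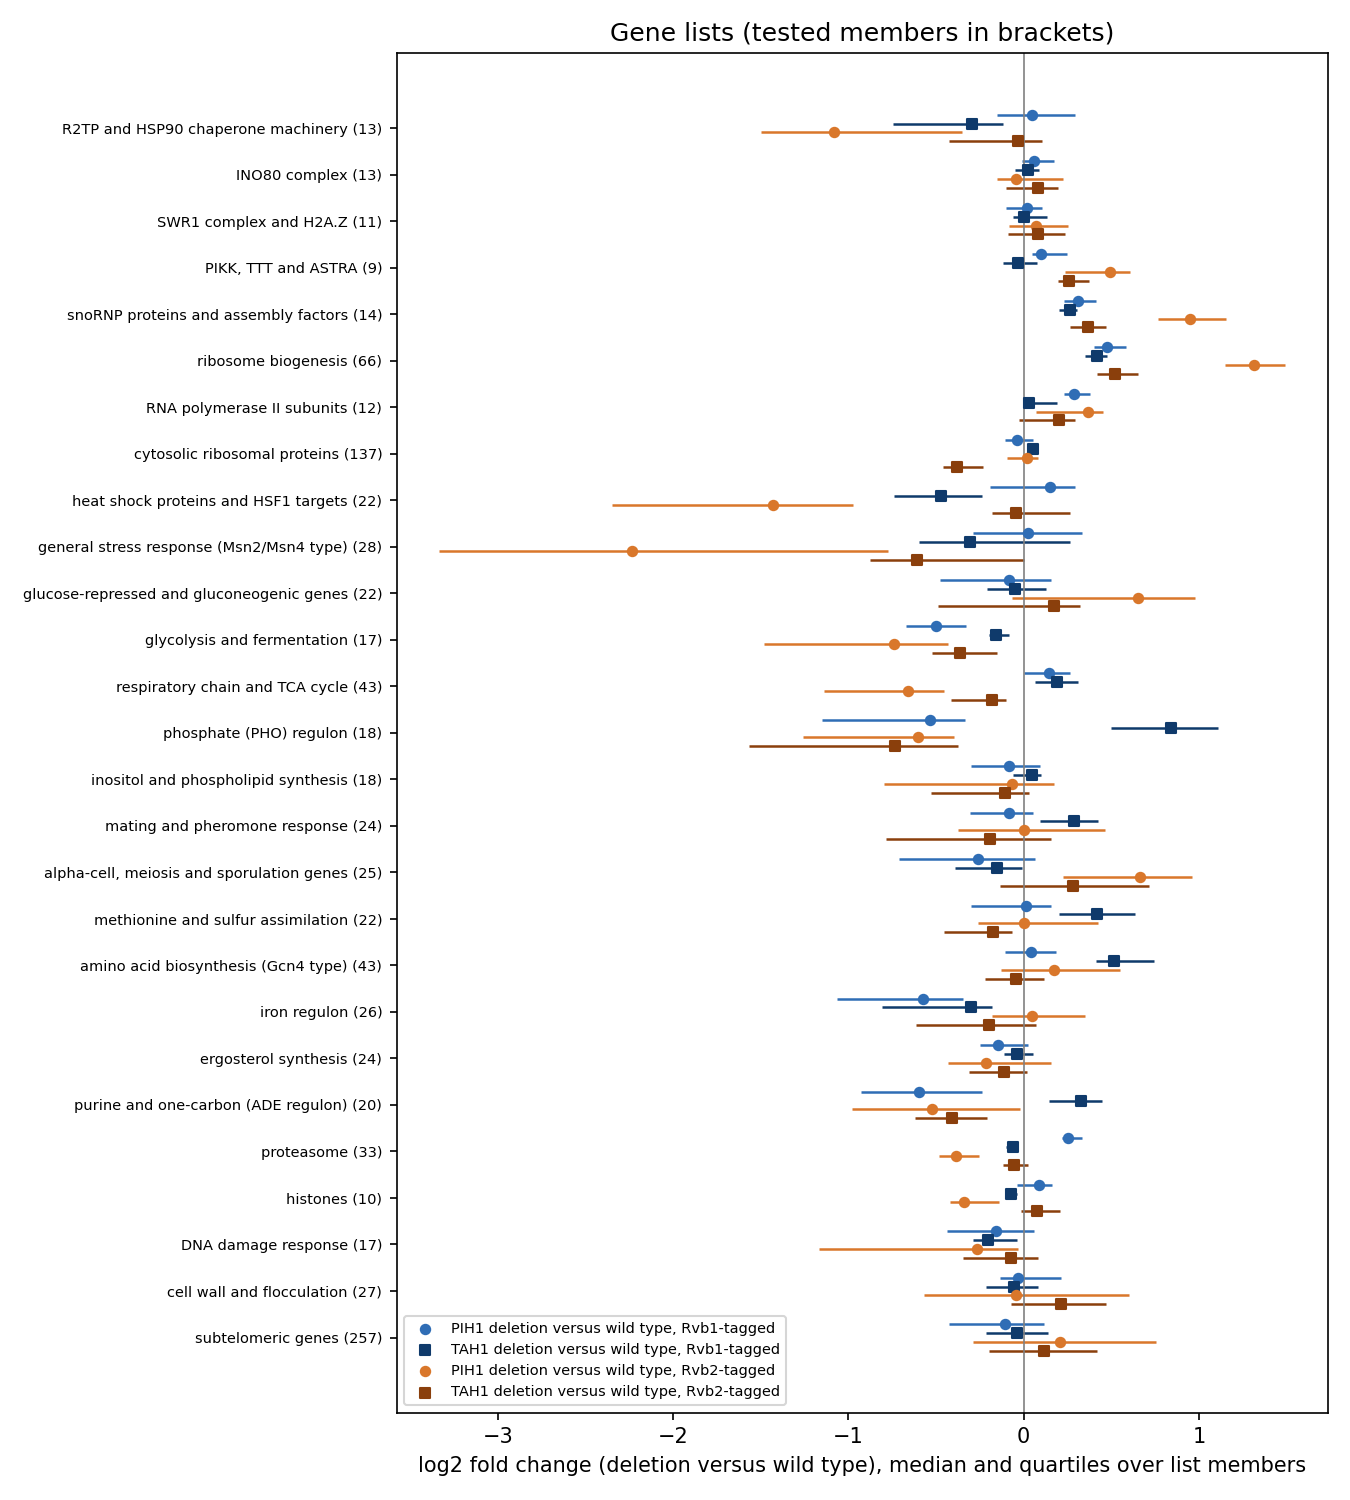
Median log2 change of each gene list (y axis, tested members in brackets) in the 4 deletion against wild type comparisons (x axis, markers), with lines from the lower to the upper quartile of the members. Ribosome biogenesis lies above 0 in all 4 comparisons (0.48, 0.42, 1.31 and 0.52), and the phosphate list lies at 0.84 in the Rvb1-tagged TAH1 deletion and at -0.53, -0.61 and -0.74 in the others. The deletions of a background share their wild type libraries, and ribosome biogenesis also differed between the wild types by camera at the preset correlation.

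The loss of PIH1 was compared between backgrounds to see which changes both share. In both, 745 genes rose and 730 fell, 1475 against 770 expected for independent lists, and 253 went opposite ways. Across genes, which are not independent replicates, the changes correlated at r = 0.49. Simulated unchanged groups, with the noise of each gene drawn independently, gave 0.000337. The largest shared rises, Rvb1-tagged first, were those of snR17a (2.08 and 5.25), LSR1 (1.25 and 1.76), snR57 (1.22 and 1.26), RGS2, a regulator of G-protein signalling (1.21 and 1.49), and YDL186W (1.09 and 1.84). The largest shared falls were those of TIR1 (-2.64 and -2.54), CIS1 (-3.07 and -2.52), PHO12 (-2.56 and -2.41), RPL8A (-2.10 and -3.11) and TDH2 (-2.07 and -2.21). Fits of only the libraries compared gave 843 shared genes, and library weights 2427. The loss of TAH1 shared fewer: 133 genes rose and 128 fell in both backgrounds, 261 against 141 expected, and 112 went opposite ways (r = 0.26 across genes). HSP12 (2.58 and 1.89), snR17a (1.69 and 2.44), HXT4 (1.42 and 1.97) and YPL025C (1.11 and 1.99) rose most, the last on chromosome XVI, whose genes shifted by 0.94 with tagged Rvb2, and CIS1 (-2.46 and -2.01), FIT2 (-2.08 and -1.89), TMA10 (-1.85 and -2.29), PDR5 (-2.05 and -1.75) and EMI2 (-1.26 and -1.30) fell most. YBL005W-B, of a Ty element and overlapping YBL005W-A, was at 1.35 and 1.68. With tagged Rvb1, EMI2 missed the threshold without wild type replicate 1 (adjusted p = 0.0979) or 3 (adjusted p = 0.0928), or TAH1 deletion replicate 2 (adjusted p = 0.0528) or 3 (adjusted p = 0.0638). HSP12 with tagged Rvb1 was at 1.83 and 3.31 without TAH1 deletion replicates 1 and 2. With only the libraries compared EMI2 and YPL025C missed the threshold with tagged Rvb1 (adjusted p = 0.172 and 0.0988). The TAH1 count was 988 without Rvb1-tagged wild type replicate 2, 122 without replicate 1, 120 without replicate 3, and 150, 158 and 156 without TAH1 deletion replicates 1, 2 and 3. It was 37 in fits of only the libraries compared and 1323 with library weights, and quantile normalization split it as 86 higher and 195 lower.

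Set against each other with tagged Rvb1, the deletions differed in phosphate genes. PHO12 (-3.58 ± 0.23), PHM6 (-3.34 ± 0.27), IMD2 (-3.23 ± 0.13), PHO89 (-3.15 ± 0.50) and PHO84 (-2.85 ± 0.11) were lower in the PIH1 deletion, PHO84 at 2345 ± 74.6 against 16944 ± 675. CYC7, a cytochrome c isoform (2.03 ± 0.54), 21S_rRNA (1.98 ± 0.55), HSP42 (1.83 ± 0.49), YML122C (1.66 ± 0.24, overlapping YNCM0001W) and YDR215C (1.6 ± 0.47) were higher. Without TAH1 deletion replicate 1 CYC7 was at 2.63, and without replicate 2 PHO89 at -3.93. With FPKM values the change of 21S_rRNA was 1.06 (adjusted p = 0.0651). With limma, 1543 genes passed, 698 higher in the PIH1 deletion and 845 lower. Without TAH1 deletion replicate 3 the adjusted p was 0.0571 for CYC7, 0.0506 for HSP42, 0.0589 for 21S_rRNA and 0.0647 for YDR215C. Without PIH1 deletion replicate 3 it was 0.0637 for 21S_rRNA and 0.0530 for YDR215C, and for YDR215C 0.0602 without PIH1 deletion replicate 1 and 0.0858 without TAH1 deletion replicate 1. The phosphate list had 16 of 18 lower and 1 higher, the same numbers adjusted over the list alone (median -1.37, camera adjusted p = 2.3e-18; adjusted p = 0.043 with an estimated correlation). Purine genes were lower in 16 of 20 cases, 17 adjusted over the list alone (camera adjusted p = 2.7e-16; adjusted p = 0.13 with an estimated correlation), and amino acid genes in 35 of 43, 36 adjusted over the list alone (camera adjusted p = 8.5e-16; adjusted p = 0.39 with an estimated correlation). Proteasome genes were higher in 31 of 33 cases, 32 adjusted over the list alone (camera adjusted p = 2.3e-18; adjusted p = 0.17 with an estimated correlation), and heat shock genes in 13 of 22, 14 adjusted over the list alone (camera adjusted p = 3.9e-06; adjusted p = 0.46 with an estimated correlation).

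With tagged Rvb2 the deletions differed in 3629 genes, 1674 higher in the PIH1 deletion and 1955 lower. The snoRNAs snR37 (4.19 ± 0.30), snR30 (3.84 ± 0.16), snR13 (3.42 ± 0.48) and snR8 (3.17 ± 0.25), and YOL118C (3.16 ± 0.25), were higher in the PIH1 deletion. HSP82 (-4.68 ± 0.36) and GPH1, glycogen phosphorylase (-4.20 ± 0.68), both on chromosome XVI, YGP1, a secreted glycoprotein (-4.16 ± 0.23), HXK1 (-4.00 ± 0.36) and HXT4 (-3.54 ± 0.19) were lower. HSP82 stood at 224 ± 12.5 against 5779 ± 266. Heat shock genes were lower in 20 of 22 cases and higher in 1, the same numbers adjusted over the list alone (median -1.31, camera adjusted p = 3.5e-08; adjusted p = 0.39 with an estimated correlation). Ribosomal protein genes were higher in 107 of 137 cases and lower in 15, 110 and 15 adjusted over the list alone (median 0.39, camera adjusted p = 4.0e-10; adjusted p = 0.60 with an estimated correlation). Respiratory genes were lower in 35 of 43 cases, 36 adjusted over the list alone (camera adjusted p = 5.3e-08; adjusted p = 0.52 with an estimated correlation). The phosphate list, with 8 of 18 higher and 3 lower (the same numbers adjusted over the list alone), did not pass camera (adjusted p = 0.39). Chromosome XVI stood higher in the TAH1 deletion, as given above.

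Calls shared by both deletions were counted in each background. With tagged Rvb1, 149 genes rose and 178 fell in both, 327 against 119 expected, and 63 went opposite ways. The changes correlated across genes at r = 0.48, where unchanged groups with a shared wild type gave 0.50. The covariance was 0.0603 against 0.0105. With tagged Rvb2, 966 rose and 895 fell in both, 1861 against 902 expected, and 213 went opposite ways, with r = 0.56 against 0.50 and a covariance of 0.220 against 0.0105. Part of the excess can come from the shared wild type libraries, 3 per background, which cannot be divided between the deletions. The simulations, run with limma, gave 0 shared calls. They drew the noise of each gene independently, without deviations common to many genes of a library. They therefore cannot show how many shared calls the common wild type libraries give. The Rvb1 count was 1251 without wild type replicate 2, 146 without replicate 1, 136 without replicate 3, and 193, 203 and 195 without TAH1 deletion replicates 1, 2 and 3. It was 39 in fits of only the libraries compared and 1602 with library weights, and quantile normalization split it as 104 higher and 198 lower. Library weights gave 2828 with tagged Rvb2. Among the genes lowered in all 4 deletions, chosen after their values were seen, were PDR5 (-2.22, -2.05, -1.95 and -1.75 in the PIH1 and TAH1 deletions with tagged Rvb1, then tagged Rvb2) and URA1 (-1.47, -1.07, -1.79 and -2.50).

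The wild types, which differ by the tag per the labels, differed in 12 of 5825 genes with limma, 5 higher and 7 lower with tagged Rvb2, and 1375 had an unadjusted p under 0.05. The agglutinin genes AGA2 (0.55 ± 0.08, adjusted p = 0.0098) and AGA1 (0.45 ± 0.08, adjusted p = 0.027), the cell fusion gene PRM1 (0.58 ± 0.11), the repressor gene YOX1 (0.40 ± 0.07) and YFR006W (0.30 ± 0.06) were higher. FIT3 (-0.54 ± 0.08), TRA1 (-0.47 ± 0.08), MCH5 (-0.41 ± 0.07), ARN1 (-0.39 ± 0.08), TCB2 (-0.38 ± 0.08), BUD4 (-0.32 ± 0.06) and NDE1 (-0.28 ± 0.05) were lower. RVB1 (-0.12 ± 0.08, adjusted p = 0.39) and RVB2 (-0.06 ± 0.07, adjusted p = 0.65) did not pass. Ribosome biogenesis genes had a median of -0.37 with 0 genes past limma's threshold, 48 at an unadjusted p under 0.05 and 39 lower adjusted over the list alone (camera adjusted p = 8.9e-18; adjusted p = 0.47 with an estimated correlation). General stress genes had a median of 0.70, with 7 of 28 at an unadjusted p under 0.05 and 0 past limma's threshold, adjusted over the list alone too (camera adjusted p = 9.3e-07; adjusted p = 0.53 with an estimated correlation). The Rvb1-tagged wild type was not uniform in such genes. TSL1 stood at 343 in replicate 2, against 2400 and 2259 in replicates 1 and 3 and 2142 to 2578 with tagged Rvb2. HSP42 stood at 127, against 806 and 749 and 912 to 949. Both were chosen after their values were seen. Mating genes were higher in 3 of 24 cases, 9 adjusted over the list alone (camera adjusted p = 9.7e-06; adjusted p = 0.15 with an estimated correlation). None of the 12 calls held in a fit of only these 6 libraries, where each gene had an adjusted p = 0.538 and limma gave 0 calls. Library weights gave 1151 calls, TMM scaling 7, FPKM values 5 and a replicate block 7. Leaving out 1 library gave 472 (Rvb1-tagged replicate 1), 6 (Rvb1-tagged replicate 2), 313 (Rvb1-tagged replicate 3), 1 (Rvb2-tagged replicate 2) and 45 calls (Rvb2-tagged replicate 3). Without Rvb2-tagged replicate 2 AGA2 alone passed, and the other 11 had adjusted p values of up to 0.126 (ARN1). Without Rvb2-tagged replicate 1 they reached 0.155 (TCB2), without Rvb1-tagged replicate 2 0.142 (PRM1), and without Rvb2-tagged replicate 3 0.0521 (PRM1 and YFR006W).

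Whether a deletion acted differently between backgrounds was tested as the difference of its effects. For PIH1, 2932 genes passed limma's threshold, 1495 with a higher change and 1437 with a lower change with tagged Rvb2. Respiratory genes differed in all 43 cases, adjusted over the list alone too, with a median difference of -0.80 (camera adjusted p = 2.2e-17; adjusted p = 0.35 with an estimated correlation). Proteasome genes differed downward in 32 of 33 cases, and 32 adjusted over the list alone (camera adjusted p = 5.4e-16; adjusted p = 0.21 with an estimated correlation), heat shock genes in 19 of 22, 20 adjusted over the list alone (camera adjusted p = 1.4e-09; adjusted p = 0.37 with an estimated correlation), and general stress genes in 23 of 28, 24 adjusted over the list alone (camera adjusted p = 3.8e-07; adjusted p = 0.53 with an estimated correlation). Iron genes differed upward in 23 of 26 cases, and 23 adjusted over the list alone (median 0.71, camera adjusted p = 6.3e-08; adjusted p = 0.14 with an estimated correlation). For TAH1, 1426 genes passed, 756 higher and 670 lower, and without the genes of chromosome XVI 916, 313 higher and 603 lower. Library weights gave 2506. The phosphate list differed downward in 15 of 18 cases and upward in 1, the same numbers adjusted over the list alone, with a median of -1.94 (camera adjusted p = 8.5e-16; adjusted p = 0.043 with an estimated correlation). Ribosomal protein genes differed downward in 91 of 137 cases and upward in 9, 104 and 9 adjusted over the list alone (camera adjusted p = 5.5e-17; adjusted p = 0.52 with an estimated correlation), and amino acid genes downward in 32 of 43, 36 adjusted over the list alone (camera adjusted p = 2.0e-14; adjusted p = 0.39 with an estimated correlation).

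INO80 and SWR1 genes, whose products work in complexes with Rvb1 and Rvb2, did not pass camera in any of the 9 contrasts. In the order of the deletions above, 3, 0, 4 and 3 of 13 INO80 genes rose with limma and 0, 0, 2 and 1 fell, and 2, 0, 5 and 2 of 11 SWR1 genes rose and 2, 0, 1 and 0 fell; adjusted over the list alone the numbers were the same. INO80 itself rose by 0.37 ± 0.08 and the histone variant gene HTZ1 fell by -0.63 ± 0.07 in the Rvb2-tagged PIH1 deletion. The cell wall list did not pass in the 9 contrasts either. Of the BY4741 auxotrophy loci, LEU2, MET17 and URA3 were listed at 0 in all libraries, and HIS3 changed by 0.19, 0.73, 0.18 and 0.30 in the 4 deletions.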

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

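The tests of the differences between backgrounds were chosen before the data were examined, while all splits of the libraries and the tests on the tagged transcripts other than these were chosen after the results were seen. The results here are those whose effect differed between the backgrounds in a test of the difference itself. For the PIH1 deletion 2932 genes passed, and 12 gene lists passed camera at the preset correlation. With an estimated correlation none of the 12 passed camera (adjusted p = 0.13 to 0.53). The change was higher with tagged Rvb2 for the snoRNAs snR30 (3.94), snR37 (3.59), snR45 (3.56) and snR32 (3.37), and for YAR053W (3.37). It was lower for SOL4 (-4.99), HXT7 (-4.56), COX26 (-4.07), HSP42 (-4.07) and HSP82 (-3.95). Without replicate 2 of the Rvb1-tagged wild type these were smaller for SOL4 (-3.61), COX26 (-3.15), HSP42 (-3.20) and HSP82 (-3.22). SOL4 was at -5.71 and -5.64 without replicates 1 and 3 of that wild type. COX26 was at -4.74 without Rvb1-tagged PIH1 deletion replicate 1 and -4.70 without Rvb2-tagged PIH1 deletion replicate 3. YAR053W was at 2.73 without Rvb2-tagged wild type replicate 3. RVB1 differed by 1.45 and RVB2 by -1.68. Of the genes named for the PIH1 deletions, 33 of 45 passed the test of the difference.

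For the TAH1 deletion 1426 genes passed, and 12 gene lists passed camera at the preset correlation. With an estimated correlation only the phosphate list passed camera, and the others had adjusted p = 0.13 to 0.60. The change was higher with tagged Rvb2 for YGR139W (3.44), TDA6 (3.29), YPR145C-A (3.14), GUP2 (3.01) and PES4 (2.93), of which TDA6, YPR145C-A and GUP2 lie on chromosome XVI. YGR139W was at 2.74 and 4.33 without Rvb2-tagged wild type replicates 1 and 3. The change was lower for the phosphate genes SPL2 (-6.00), PHO84 (-5.67), PHO12 (-3.15), PHO89 (-2.96) and PHO5 (-2.73). PHO89 was at -3.75 without Rvb1-tagged TAH1 deletion replicate 2. RVB1 differed by 1.83 and RVB2 by -0.80. Of the genes named for the TAH1 deletions, 24 of 41 passed the test of the difference. These differences cannot be divided between a different action of TAH1 loss and the chromosome XVI shift of the Rvb2-tagged TAH1 deletion.

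Other splits of the libraries were counted for each of these results. For the PIH1 difference 5 of 100 splits gave as many genes, so chance is not excluded by this count. The highest other split gave 3899 against 2932. The 4 other splits with as many genes were not groups without change: those with 2982, 3899 and 2991 exchanged all 6 labels of the Rvb2-tagged libraries, which turns the effect there around, and that with 3014 exchanged 4 of the 6 Rvb1 labels. For the TAH1 difference 3 of 100 splits did, with 1426 genes and 2542 in the highest other split. In the splits with more genes (2542 and 2365) all 6 labels of 1 background were exchanged, which turns its effect around. A split that turns an effect around is not one without change, so neither share can decide on chance.

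The transcript of the tagged gene fell in the deletion strains, and the other one did not. Scaling of the libraries is argued against, since RVB1 and RVB2 moved 2.37 apart within the Rvb2-tagged PIH1 deletion. Between the wild types 12 genes differed, or 1 to 472 with 1 library left out, and the tag itself is not seen in the tables. Wild type libraries from strains without the tags thus cannot be told apart from tagged ones. A tag that lowers its own transcript in every tagged strain cannot be told apart either. The larger wild type difference of RVB1 and RVB2, -0.12, would argue against it only if the wild types carry the tags. An equal effect of the tag would not by itself account for RVB1 in the Rvb1-tagged deletions, which lay 0.39 higher in the PIH1 than in the TAH1 deletion (adjusted p = 0.0023). That the deletions act on the tagged allele stays open as a hypothesis, which was not tested here.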

How the results depend on the processing

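The fit without the genes of chromosome XVI and the lists without PIH1 and TAH1 were chosen after the data were seen, the other alternatives before. Count-based tests on recovered reads were not run, since whole reads could not be recovered from the rounded values. Where 1 library is left out of 3, limma pools the spread over all groups. Scaling moved the median of all genes by at most 0.074.

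In fits of only the libraries compared the calls were 1277 for the PIH1 deletion and 74 for the TAH1 deletion with tagged Rvb1. For the wild types limma then gave 0 (1375 at an unadjusted p under 0.05 in the model of all libraries). The shared calls were 843 (PIH1, both tags), 37 (TAH1, both tags) and 39 (both deletions, Rvb1-tagged). Library weights gave 2368 for the TAH1 deletion with tagged Rvb1, 1151 for the wild types and 2506 for the TAH1 difference between backgrounds. They gave shared calls of 2427 (PIH1, both tags), 1323 (TAH1, both tags), 1602 (both deletions, Rvb1-tagged) and 2828 (both deletions, Rvb2-tagged). For the wild types TMM scaling gave 7, and FPKM values gave 5. Without the genes of chromosome XVI the TAH1 difference had 916. Of 118 list calls, 4 passed with an estimated correlation, and 4 with both this and lists without PIH1 and TAH1.

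Leaving out 1 library moved the TAH1 deletion with tagged Rvb1 from 296 to 1827, the wild types from 1 to 472, the shared TAH1 calls from 120 to 988 and those of both deletions with tagged Rvb1 from 136 to 1251. The highest came without Rvb1-tagged wild type replicate 2, except for the wild types (replicate 1). The PIH1 deletion with tagged Rvb1 went from 1597 to 2706. A replicate block for the shared replicate numbers gave 7 for the wild types.

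RVB2 in the Rvb1-tagged PIH1 deletion (0.19) was 0.18 with TMM, 0.0937 with quantile normalization, 0.19 with only the libraries compared (adjusted p = 0.0534, 0.310 and 0.0900) and 0.14 to 0.23 with 1 library left out. TAH1 in the Rvb2-tagged PIH1 deletion (0.29) passed with a pseudocount of 5 (0.29), quantile normalization (0.40), only the libraries compared (0.29) and library weights (0.35).

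Direction turned for 4 list medians. In the Rvb1-tagged PIH1 deletion heat shock genes ranged from -0.15 to 0.30 with 1 library left out, and general stress genes from -0.49 to 0.24. Ribosomal protein genes in PIH1 against TAH1 deletion with tagged Rvb1 went from -0.08 to 0.0133 with quantile normalization. Between the wild types they ranged from -0.17 to 0.00371 with 1 library left out. Of 118 called list tests, 92 held in every alternative with the preset correlation. Of 183 results of named genes, 144 held in every alternative, 39 changed and none turned direction.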

Other observations

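The tests of the chromosome by stretches and by library, and of short RNA, were chosen before their results were seen. The other tests here, the genes called in all 4 deletions and all splits of the libraries were chosen after the results were seen.

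The genes of chromosome XVI rose together in the Rvb2-tagged TAH1 deletion. A change of 1 part of the chromosome is argued against, since all 10 stretches had a median above 0.5 (0.881 to 1.05). A single library is argued against as well, since the lowest of the 3 TAH1 deletion libraries stood at 0.933. An extra copy of the whole chromosome, in a strain with 1 copy of the others, may explain the shift of 0.943, and was proposed after the shift was seen. It would leave RVB2, at -0.76 on this chromosome against the wild type, as an exception. Against the PIH1 deletion with tagged Rvb2, RVB2 was higher (521 against 311), as was the chromosome (median of PIH1 against TAH1 deletion -0.94). Whether the deletion or the history of the strain brought an extra copy was not tested.

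RNAs without a poly(A) tail rose in the Rvb2-tagged PIH1 deletion, among them snR17a and snR30. Protein-coding genes of at most 300 bp lay -0.135 from longer ones. Their transcripts carry poly(A) tails and exceed the annotated span, so this cannot decide on a loss of short RNA from the other libraries. A change limited to box C/D snoRNAs is argued against, since box H/ACA snoRNAs had a median of 2.09. More carry-over of RNA without a tail may explain the rise, since 6 such RNAs that are no snoRNAs had a median of 1.88, and an effect of PIH1 loss on snoRNA levels stays open beside it. The members moved unequally, from -0.50 to 5.25 for box C/D, -0.32 to 4.67 for box H/ACA and 0.90 to 2.95 for the other 6. Equal carry-over of all such RNAs would not account for this spread. Carry-over that differs between such RNAs, for example by length, was not tested. The spread therefore cannot tell it from an effect of PIH1 loss. For snR17a in the Rvb2-tagged TAH1 deletion (2.44), a median of 0.164 in the other 50 RNAs argues against equal carry-over only.

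In all 4 deletions 253 genes were called, 88 of them higher (5.91 expected for independent lists) and 99 lower (3.46 expected); the deletions of a background share their wild type libraries. snR17a rose by 2.08, 1.69, 5.25 and 2.44, in the order PIH1 and TAH1 deletion with tagged Rvb1, then with tagged Rvb2. RGS2 rose by 1.21, 1.05, 1.49 and 1.55. YHR033W, beside PIH1, rose in the TAH1 deletions too (0.64 and 1.05). CIS1 fell by -3.07, -2.46, -2.52 and -2.01, and the iron gene FIT2 by -2.73, -2.08, -1.51 and -1.89. The efflux pump gene PDR5 fell from 13225 ± 830 to 2826 ± 94.1 and 3200 ± 75.1 with tagged Rvb1. With tagged Rvb2 it fell from 11175 ± 1463 to 2883 ± 103 and 3300 ± 76.4. Its regulator genes changed less: PDR1 by 0.18, -0.14, 0.24 and -0.30, and PDR3 by -0.39, -0.47, 0.43 and -0.16.

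Other splits of the libraries were counted for the remaining results. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 2211 and 417 for the PIH1 deletion with tagged Rvb1 (1 of 10 as large), and 627 and 654 for the TAH1 deletion (2 of 10). With tagged Rvb2 they were 4054 and 0 for PIH1 (1 of 10), and 2589 and 1 for TAH1 (1 of 10). For PIH1 against TAH1 deletion they were 1543 and 16 with tagged Rvb1 (1 of 10) and 3629 and 0 with tagged Rvb2 (1 of 10), and for the wild types 12 and 0 (1 of 10). The 0 counts are from limma.

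For shared calls 100 splits were drawn. For the PIH1 deletion in both backgrounds the share was under 0.05 (1 of 100, with 1475 calls and 398 in the highest other split). It shows that the labelled groups differ, and cannot tell the loss of PIH1 from other differences between the strains. For the TAH1 deletion the share was under 0.05 too (261, highest other 290; 2 of 100), but the other split gave more calls than the real one. It exchanged replicate 2 of the Rvb1-tagged wild type with replicate 2 of the TAH1 deletion and kept the Rvb2 labels. For both deletions it was 2 of 100 with tagged Rvb1 (327, highest other 1023) and with tagged Rvb2 (1861, highest other 2739). A split with 1023 calls, several times 327, points to a structure of the samples. In it, and in that with 2739, the 3 PIH1 deletion libraries took the place of the wild type, and wild type and TAH1 deletion libraries were mixed in the other 2 groups.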
